A study of Saccharomyces cerevisiae with 180 samples.

How the data were processed

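RNA of 90 yeast cultures was compared with 1 reference pool of strain BY4716 on 180 arrays with 2 colours. Each culture was hybridised on 2 arrays with the dyes exchanged. The cultures were 2 of the laboratory strain BY4716, 2 of the vineyard strain RM11 and 86 haploid segregants. The labels give the parents of the segregants as BY4716 and RM11-1a, which was taken as the strain that the parental cultures call RM11.

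The deposited values are log ratios of the culture over the reference pool, read as log2 ratios. The base of the logarithm is not stated. In base 2 the lowest value is a 2482-fold difference, whereas in natural logarithm it would be 78991-fold, above the range of 65536 of a 16-bit scanner. The authors centred every array on a mean of 0, and the array medians lay between -0.063 and 0.074. The deposited values already pointed the same way in both dye orientations. Scanner, background correction, spot filter and dye normalization are not stated. The direction of the ratios was set by 12 strain marker genes, of which 12 went the way the genotypes require, so these genes are no finding of direction. BY4716 has mating type alpha and lacks LYS2, and RM11 has mating type a and lacks LEU2, URA3 and HO.

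The table held 7085 probes. A single gene symbol was paired with 5645 of them, and 1440 had none, of which 267 had no value on any array. All 5645 gene identifiers matched the RefSeq gene table of assembly R64, which was used for names and neighbours only. Probes of the same gene were averaged, which gave 5605 genes, 40 of them with 2 probes. Where only 1 of the 2 had a value on an array, that value was used. An array held between 3769 and 6570 values, with a median of 6288.5, and 923 probes had a value on every array. Signal intensities were not used here, so the precision rests on the number of arrays and cultures. No positions in the genome were taken from the files.

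Both arrays of a culture were averaged, so that each culture was 1 replicate. RM11 was compared with BY4716 with limma 3.58.1 in R 4.3.3 on the 4 parental cultures, for genes with a value on all 8 parental arrays, at a Benjamini-Hochberg adjusted p under 0.05. The BY4716 cultures were compared with the pool in the same fit; the pool is a single sample, so its own spread was not included. A one-sided F test set the variance over segregants against the variance between cultures of the same parent, moderated with limma, with 5.28 degrees of freedom, for genes with values in at least 80 percent of segregants. The segregant mean was compared with the midpoint of the parental means with a moderated test that combined both variances. Normal mixtures were fitted with mclust 6.1.1. Segregants were called as falling in 2 clusters where the BIC favoured them by over 10, the means lay over 4 component SDs apart and the smaller cluster held at least 20 percent of the segregants. Cluster sizes were compared with equal sizes by an exact two-sided binomial test.

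A set of 26 gene lists was tested between parents with camera at a preset correlation of 0.01, with an estimated correlation and with fry, for lists of at least 3 measured genes. Co-variation of a list was its mean pairwise Pearson r over segregants, compared with 10000 random lists matched on SD, for lists of at least 5 genes. List scores were the mean over members of values centred and scaled per gene. Pairs of scores without shared members were compared by Pearson and Spearman correlation with 100000 permutations. Genes past the variance test were joined by average linkage, and the tree was divided at r = 0.7. Neighbouring genes were those adjacent by systematic name on the same chromosome arm, and their mean r was compared with 10000 permutations of positions.

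Lists, groups and the rule for naming genes were chosen before the data were examined. So were tests and alternatives, except those named in the closing section as chosen later, the comparisons of clusters with chromosomes and probe numbers and the test of the orientation of neighbours. The rule took the 15 largest rises and 15 largest falls between parents with the same sign in every pair of cultures, the 20 largest segregant SDs, the 15 clearest cases of 2 clusters, and the 5 highest and 5 lowest genes against the midpoint. It added up to 2 rising and 2 falling members of a list, or the 3 members with the highest mean r, together with the strain markers and LEU2, URA3, LYS2, GPA1, AMN1, HAP1, MATALPHA1 and FLO11. Alternatives covered array centring, quantile normalization, single dyes, left-out cultures, a block for the culture number, filters on missing values, the error estimate, the first number of the segregant titles, removal of the first principal component and the limits of each call. No covariates were used, since the labels name none.

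The steps were tested on simulated data, with 3193 genes except for the mixtures. With the spread of the real genes, limma recovered 91.4 percent of simulated 1.5-fold differences between parents and 99.6 percent of 2-fold ones, and 5.10 and 6.31 percent of its calls were false. The variance test then recovered 91.2 and 99.7 percent of changed genes, but 10.2 and 12.3 percent of its calls were false, above the nominal 5 percent. With spreads drawn from the fitted distribution its false share was 3.95 percent at the 2-fold size, and it recovered 0 percent of changes at the 1.5-fold and 85.4 percent at the 2-fold size. For the midpoint test the false share was 6.22 and 6.34 percent, and 8.05 percent at the 1.5-fold size with fitted spreads. In these simulated sets genes varied independently, with the same error SD in every culture. In the data the RM11 pair gave the larger error, since calls rose without either RM11 culture and fell without either BY4716 culture. These shares therefore need not carry over to the data. For the mixtures, with 200 simulated genes at each separation, 56 percent of genes in 2 clusters were recovered at 4 component SDs, the limit used, and 98.5 percent at 5. Of 5000 simulated genes without clusters, 0 were called with normal and 2 with skewed values.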

Results

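The data were log2 ratios of transcript levels in 90 cultures of Saccharomyces cerevisiae, each over the same BY4716 reference pool. There were 2 cultures of BY4716, 2 of RM11 and 86 segregants, and each culture had 2 arrays. The arrays of a pair correlated across genes with r of 0.896 and 0.831 for the RM11 cultures, and with a median of 0.725 for the segregants, from 0.371 to 0.896. For the BY4716 cultures, the same strain as the pool, r was 0.109 and 0.0232. Genes are not independent replicates, so these values describe the arrays only. The series addresses how regulatory variation between the parents changes transcript levels in their progeny.

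The first comparison asked which transcripts differed between the parents. In RM11, 10 of 12 measured genes of leucine and branched-chain amino acid synthesis passed as higher, 5 of 6 of pyrimidine synthesis, 15 of 22 of ergosterol synthesis, 27 of 30 of the respiratory chain and 33 of 48 of the mitochondrial ribosome. As lower passed 7 of 10 genes of daughter cell separation, 6 of 9 of glycolysis, 6 of 12 of purine synthesis and 6 of 6 alpha-specific mating genes, whose direction follows from the mating types. RM11 also lacks LEU2 and URA3, genes of leucine and pyrimidine synthesis. In the parents, effects of these deletions on the other genes of both pathways cannot be told apart from other strain differences. These 9 lists were called by camera at its preset correlation and none of them with an estimated correlation, where the adjusted p lay between 0.408 and 0.534. LEU1, an enzyme of leucine synthesis, was higher by 3.49 log2 units (SE 0.19, 2 cultures per strain), or 11.2-fold. URA1, an enzyme of pyrimidine synthesis, was higher by 3.03 (SE 0.14), and RIP1, a subunit of the respiratory chain, by 1.99 (SE 0.08). DSE2, which acts in the separation of daughter from mother cells, was lower by 5.59 (log2 -5.59, SE 0.14). The RM11 means of DSE2 (-5.51) and of DSE1 (-5.72), given below, were close to those of genes that RM11 lacks. These were LEU2 (-5.68), URA3 (-4.66) and HO (-4.37). The sizes of the falls of DSE2 and DSE1 therefore depend on the lower limit of the signal.

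The gene with the largest rise outside the strain markers was PUT4, the proline permease, at 5.07 log2 units (SE 0.09). Other large rises were AGA2, an a-specific mating gene, at 3.68, SCM4 at 2.79 and OAC1, of the leucine list, at 2.58. The direction of AGA2 follows from the mating types. FMP45 stood at 2.51, CTT1, the cytosolic catalase, at 2.48 and MAE1, the malic enzyme, at 2.42. RTN2 followed at 2.32, AGX1 at 2.23, PLN1 at 2.07 and FMP48 at 1.97. The receptor gene STE2, a strain marker, stood at 5.57 (SE 0.23). The largest falls were in the retrotransposon genes YBR012W-B at -7.76 (SE 0.39) and YBL005W-A at -7.52 (SE 0.15), with YDR170W-A at -6.01, YJR029W at -5.82 and YMR045C at -5.36. The asparaginase genes ASP3-3, ASP3-2 and ASP3-1 stood at -6.60, -6.45 and -5.98, and the hexose transporter gene HXT13 at -4.69. The RM11 means of the asparaginase genes, -6.49, -6.62 and -5.86, lay below that of LEU2 (-5.68), which RM11 lacks. The size and order of their falls therefore depend on the lower limit of the signal. Across segregants HXT13, examined further after its values were seen, fell in a cluster with YDR170W-A, YMR045C, YBL005W-A, YMR158C-A, BPH1 and MOB2, the last an average of 2 probes that did not agree, and no other hexose transporter gene. The cause was not tested. DSE1 stood at -5.82 (SE 0.74), and without BY4716 replicate 2 its adjusted p was 0.0569 by limma. The markers LEU2, URA3 and HO were at -5.55, -4.62 and -4.29, STE3 and SAG1 at -6.20 and -6.10, and MF(ALPHA)1 and MF(ALPHA)2 at -3.31 and -1.87. HAP1, a heme-responsive activator, was lower in RM11 (log2 -1.94, SE 0.14), AMN1, an inhibitor of mitotic exit, was lower (-1.10, SE 0.08) and MATALPHA1 stood at -2.63. GPA1, a subunit of the pheromone response G protein, differed by -0.07 (SE 0.10), with a limma adjusted p of 0.617. FLO11 had no value in any parental culture.

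Of 3256 genes tested with limma, 869 passed, 591 higher and 278 lower in RM11. All 869 had the same sign in every difference between an RM11 and a BY4716 culture. With 2 cultures per strain the threshold itself requires this, so it is no separate support. The median over all genes was 0.10, and 0.06 after centring each array on its median or 0.05 after quantile normalization. The calls were 473 higher and 323 lower under the former scaling and 433 and 323 under the latter. The number of calls rested on the spread between 2 cultures per strain. It was 199 without BY4716 replicate 1, 203 without BY4716 replicate 2, 1797 without RM11 replicate 1 and 1789 without RM11 replicate 2, the lone culture being assumed to vary like the other strain. With a further minimum of a 1.5-fold difference 406 genes passed, with Cy3-titled arrays alone 533, and among genes with a value on every array 219.

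Camera called 9 of 23 lists between parents at the preset correlation. With an estimated correlation 0 of 23 passed, with adjusted p = 0.408 for the respiratory chain, 0.534 for pyrimidine and ergosterol synthesis and 0.455 for the other 6 lists, while fry called 12. The leucine and branched-chain genes, without LEU2, were led by LEU1 and OAC1, and those of pyrimidine synthesis, without URA3, by URA1 and URA4 (log2 1.49). Ergosterol synthesis included CYB5 (1.78) and ERG5 (1.56). In the respiratory chain and ATP synthase list COX5A (1.89) was among the higher genes, and 1 gene was lower, COX5B (-0.92). The mitochondrial ribosome included MRP21 (0.78) and MRPL35 (0.75). Lower genes of glycolysis and fermentation included HXK2 (-0.89) and TDH1 (-0.88), and those of purine synthesis GCV2 (-1.30) and GCV1 (-1.18), which encode glycine cleavage enzymes. Adjusted over the list alone, 10 genes of the leucine list were higher, 5 of pyrimidine synthesis, 18 of ergosterol synthesis, 28 of the respiratory chain (1 lower) and 39 of the mitochondrial ribosome. The lower counts were then 7 for daughter cell separation, 7 for glycolysis, 6 for purine synthesis and 6 for alpha-specific genes. Camera called 16 lists with Cy5-titled arrays alone, 14 after quantile normalization and 14 without BY4716 replicate 1.

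Among the lists that camera did not call, pheromone response had 2 genes higher, TEC1 (log2 0.91) and FUS3 (0.44), and 4 lower, including AGA1 (-2.75) and SST2 (-1.32), with an adjusted p of 0.0670. Methionine and sulfur assimilation had 5 higher, such as MET3 (1.74) and MET14 (1.12), and STR3 lower (-0.39), also with 0.0670. General stress response had 10 of 27 higher, led by CTT1 and RTN2, and 3 lower, among them HSP26 (-3.47) and SSA4 (-0.94). Its mean shift against other genes was 0.26, with an adjusted p of 0.219, and turned to -0.33 after quantile normalization, with an adjusted p of 0.0319. That list was called upward without BY4716 replicate 1 (0.0238) and without RM11 replicate 2 (0.000777). Amino acid starvation response had 2 higher, HIS5 (0.41) and HOM2 (0.31), and 4 lower, such as ARG3 (-1.19) and CPA1 (-1.16); its mean was -0.13, its median 0.02 and the test pointed down. Anaerobic cell wall proteins had a mean of 0.04, a median of -0.15 and a test pointing down, with PAU7 (0.46) the 1 gene of 3 that rose. Heat shock and protein folding had 3 higher and 1 lower of 13, fatty acid oxidation and peroxisome 4 higher of 7, and the proteasome 4 higher of 27. The iron regulon had 1 higher and 2 lower of 8, phosphate starvation 1 and 1 of 5, and histones 1 higher of 8. None of 60 cytosolic ribosome genes and of 6 lysine synthesis genes passed, and 1 of 50 ribosome biogenesis genes was higher, RPA14 (0.50). The a-specific list (2 of 2 higher), flocculins (1 of 2 lower, FLO1, -0.94) and sporulation (0 of 2) had too few measured genes for camera.

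**Figure D1:**
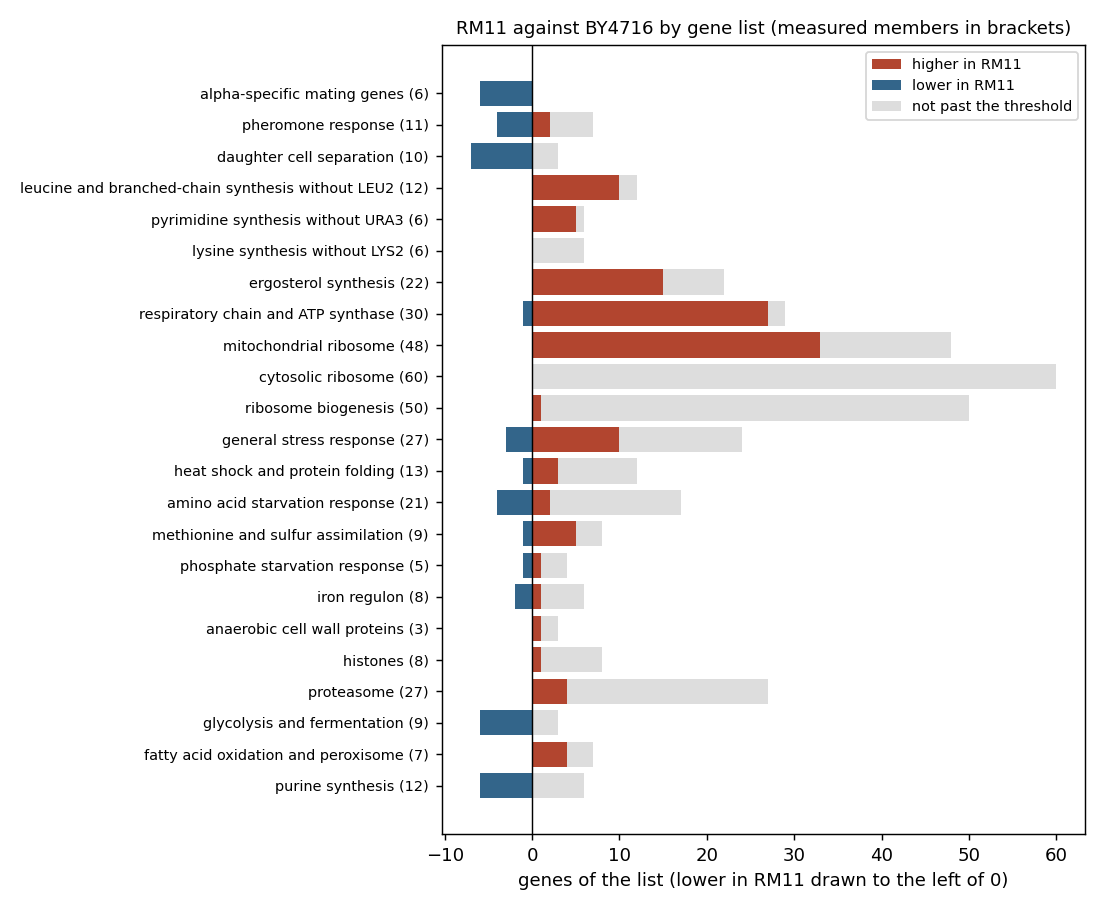
Numbers of genes in 23 lists that were higher in RM11 (red, right of 0), lower in RM11 (blue, left of 0) or not past the limma threshold (grey), with 2 cultures per strain. The mitochondrial ribosome had 33 genes higher and none lower, and the cytosolic ribosome had 0 of 60 past the threshold.

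The BY4716 cultures were then compared with the pool of the same strain, which shows what cultures alone give. MAE1, with a mean of -0.57, CTT1, with 0.66, and RTN2, with 0.53, were among the genes away from 0 in both cultures, and none passed after adjustment. Limma called 0 of 3256 genes, with a lowest adjusted p of 0.105. At an unadjusted p under 0.05 there were 616 genes, where 162.8 would arise by chance. The spread between cultures was shared with RM11 in the fit, and 1104 genes were called without RM11 replicate 1 and 1396 without RM11 replicate 2. Limma called 13 genes with Cy5-titled arrays alone and 850 after quantile normalization.

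In the segregants, the question was which transcripts varied by more than between repeat cultures of a parent. The asparaginase genes ASP3-3, ASP3-2 and ASP3-1 had segregant SDs of 3.51, 3.43 and 3.20 log2 units. As with their falls between parents, the size of these SDs depends on the lower limit of the signal. LEU2 (2.72), STE3 (2.69), URA3 (2.60), SAG1 (2.42), MF(ALPHA)1 (2.40), DSE2 (2.40), STE2 (2.39), HO (2.09), AGA2 (2.08), DSE1 (2.07) and AFB1 (1.92) also varied widely. The SDs of DSE2 and DSE1 depend on that limit as well, like those of the deleted LEU2, URA3 and HO. Outside mating type and the deleted markers, HSP12, a membrane stress protein, had an SD of 2.25 against an error of 0.159, and CTT1 had 1.72 against 0.196. ARG1, an enzyme of arginine synthesis, had an SD of 1.76, and 69 of 86 segregants lay over 2 error SDs outside the parental means. Further wide ranges were found for YIL082W-A (1.81), ZPS1 (1.59) and FMP45 (1.59). The regulators AMN1 (0.706), HAP1 (0.517) and GPA1 (0.398) also passed, with errors of 0.0800, 0.139 and 0.0984. In GPA1, which had no call between parents, 50 of 84 segregants lay outside the parental means by over 2 error SDs. The median number of such segregants was 31 over genes past the test without a call between parents. It was 14 over genes past the test with such a call, and 13 over genes not past the test.

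Of the fixed lists, general stress response had 25 of 26 genes past the test, with a median SD of 0.864 against an error of 0.153. The counts were 12 of 12 for leucine and branched-chain synthesis, 11 of 11 for pheromone response, 10 of 10 for daughter cell separation, 8 of 8 for histones and 20 of 21 for amino acid starvation response. The respiratory chain had 27 of 30 and the mitochondrial ribosome 43 of 47. Ribosome biogenesis had 17 of 50, and 0 adjusted over the list alone, and the proteasome had 7 of 27, also 0 over the list alone. In all, 1865 of 3193 genes passed, and 1163 of them had no call between parents. The median SD over genes was 0.251 against an error of 0.0936. This count rested on few parental cultures: it was 158 without BY4716 replicate 1, 139 without BY4716 replicate 2, 3261 without RM11 replicate 1, where all 3261 tested passed, and 3636 of 3637 without RM11 replicate 2. With either BY4716 culture left out most calls ended, with 152 and 127 of the 1865 kept. Of the 20 genes with the largest SDs 18 kept theirs in both cases, all but DSE1 and YIL082W-A. AMN1 kept its call, while GPA1 (adjusted p = 0.111 and 0.118) and HAP1 (0.0974 and 0.106) did not. General stress response then had 17 and 12 genes past the test, amino acid starvation response 9 and 7, leucine and branched-chain synthesis 6 and 6, the respiratory chain 5 and 4, daughter cell separation 4 and 4 and pheromone response 3 and 3. Histones, the mitochondrial ribosome, ribosome biogenesis and the proteasome had 0 and 0. The count was 631 with Cy3-titled arrays alone, 3403 with Cy5-titled arrays alone, 3100 with the error between dyes and 580 of the genes with a value on every array.

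The segregant mean was compared with the midpoint of the parents, where loci additive on the log2 scale would place it. Loci additive in the amount of transcript need not place it at that midpoint. General stress genes lay below it in 22 of 26 cases, with a median of -0.65 log2 units, and the list had none above; the medians were -0.63 after median centring and -0.86 after quantile normalization. Without BY4716 replicate 1 or 2 the list had 15 of 28 and 15 of 27 genes below, and without RM11 replicate 1 or 2 it had 21 of 26 and 27 of 27. HSP12 was lowest at -1.38 (SE 0.26, 81 segregants), then CTT1 at -1.29 (SE 0.21), SOL4 at -1.17 (SE 0.19), MSC1 at -1.15 (SE 0.19) and FMP45 at -1.11 (SE 0.20). Both BY4716 cultures and both RM11 cultures had higher stress than ribosome biogenesis list means, by 0.77, 0.66, 1.28 and 0.42, while the segregant median of that difference was -0.08. For SOL4 the BY4716 and RM11 means were 0.61 and 0.68, both above the pool. The midpoint rests on 4 parental cultures, and its error holds only the spread between cultures of the same parent. A state shared by the parental cultures therefore cannot be told apart from non-additive loci. The genes farthest above the midpoint were the retrotransposon genes YBR012W-B at 2.92 (SE 0.21), YBL005W-A at 2.82 (SE 0.12), YDR170W-A at 2.08 (SE 0.10) and YMR045C at 1.74 (SE 0.15), and the hexose transporter gene HXT13 at 1.49 (SE 0.08). YMR045C lost its call after quantile normalization, at 0.28. In RM11 these 5 genes were at -7.51 to -4.65, in or below the range of LEU2 (-5.68), URA3 (-4.66) and HO (-4.37), which RM11 lacks. Their distances from the midpoint, the SEs and their order therefore depend on the lower limit of the signal, as do their falls between parents. The respiratory chain had 6 of 30 genes below the midpoint, but 1 above and 1 below after quantile normalization, amino acid starvation response 5 above and 1 below of 21, and leucine and branched-chain synthesis 4 above of 12. With 1 parental culture left out, the median of the respiratory chain lay between -0.17 and -0.13. That of amino acid starvation response lay between 0.11 and 0.13 and that of leucine and branched-chain synthesis between 0.16 and 0.19. The counts of these lists fell without either BY4716 culture and rose without either RM11 culture.

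Of 3193 genes, 317 differed from the midpoint, 116 above and 201 below, and 213 of them had a segregant mean outside both parental means. Median centring gave 166 above and 162 below, and quantile normalization 483 and 352, so the balance of directions depended on the scaling. The count was 47 without BY4716 replicate 1, 58 without BY4716 replicate 2, 585 without RM11 replicate 1 and 1545 without RM11 replicate 2.

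Single loci of large effect would divide haploid progeny into 2 clusters of similar size. LEU2, deleted in RM11, had 44 segregants around -5.23 and 42 around 0.11, and URA3 had 43 around -5.02 and 42 around 0.03. The asparaginase genes did likewise, with 42 and 43 segregants for ASP3-3, 42 and 42 for ASP3-2, 40 and 43 for ASP3-1 and 39 and 41 for ASP3-4. Their systematic names, YLR155C to YLR160C, lie close on the same arm, so they need not be separate cases. DSE1 had 35 segregants in the lower and 51 in the upper cluster and SCW11, a glucanase of cell separation, 36 and 47. AMN1 had 37 around -1.26 and 49 around 0.03. HO, deleted in RM11, had 47 and 39. Among mating genes, STE2 had 43 and 36, STE6 37 and 39 and AFB1 34 and 48. STE3 had 33 and 53, with an exact binomial p of 0.0399, or 0.150 adjusted. SAG1, also an alpha-specific marker measured in 86 segregants, had 43 and 43. Assignment to clusters thus differed between genes of the same mating type, an error that the binomial test leaves out. The mating markers MF(ALPHA)2 and MFA1 were not called. The remaining clear cases were ENA2, a sodium pump gene, with 40 and 45, BRE4 with 38 and 47 and YJR015W with 45 and 41. URA1 and URA4 (44 and 42, and 42 and 42), chosen after their values were seen, fell into 2 clusters as well. Whether their clusters held the same segregants as those of URA3, deleted in RM11, was not compared.

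Of 5007 genes, 64 were called, and for 17 of them the cluster sizes differed from equal at an unadjusted exact binomial p under 0.05, for 11 after adjustment. Sizes compatible with 1 to 3 were found for 11 of the 17. The 20 percent limit on the smaller cluster and the choice of unequal sizes left few sizes that could depart from 1 to 3. The count therefore does not favour that ratio. Examples among the 11, chosen after their values were seen, were SEC59 with 65 and 20 segregants and SCM4 with 63 and 19. Others were ARG7 with 66 and 20 and HIS3 with 64 and 16. HAP1 and GPA1 were not called. The number of genes was 104 at a separation of 3 component SDs, 32 at 5, and 101 when the smaller cluster could hold 10 percent.

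**Figure D2:**
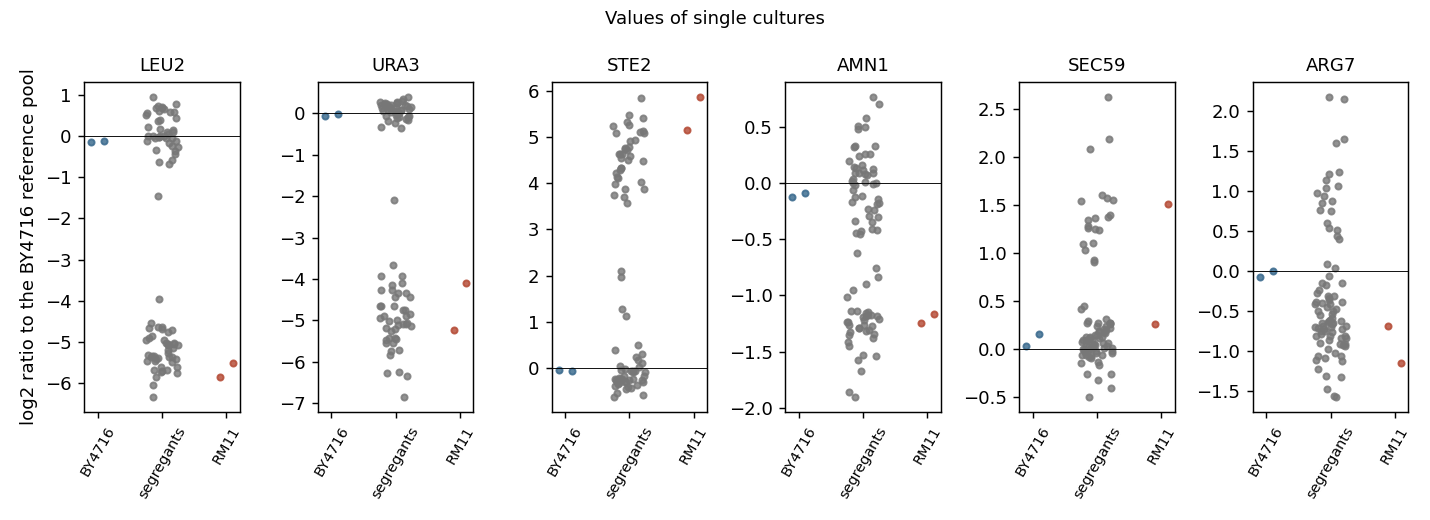
Log2 ratios over the reference pool of single cultures for 6 genes, with 2 BY4716 cultures (blue), up to 86 segregants (grey) and 2 RM11 cultures (red); points are spread sideways for legibility and each panel has its own scale. LEU2 had 44 segregants in the lower cluster and 42 in the upper, and SEC59 65 and 20.

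Across segregants, most members of functional lists rose and fell together. The mean pairwise r was 0.847 for histones, with HHF2, HHF1 and HHT1 in front, 0.816 for the cytosolic ribosome (RPL12A, RPL14A, RPL8A) and 0.722 for ribosome biogenesis (DBP3, MPP10, NOP12). Whether probes of similar genes in a list, such as HHF1 and HHF2, shared signal was not tested. General stress response had 0.689 (GAD1, TFS1, TPS2), amino acid starvation response 0.686 (HOM2, TRP3, HOM3), leucine and branched-chain synthesis 0.669 (ILV3, ILV2, LEU4), the mitochondrial ribosome 0.665 (MRPL49, MRPL8, MRPL17), lysine synthesis 0.652 (LYS20, LYS12, LYS1) and the respiratory chain 0.644 (COX4, QCR9, COX6). Phosphate starvation response had 0.512, led by PHO84, ergosterol synthesis 0.471, led by ERG2, purine synthesis 0.426, pheromone response 0.419, the proteasome 0.413, methionine and sulfur assimilation 0.409 and glycolysis 0.391. Lower values were found for anaerobic cell wall proteins (0.349), the iron regulon (0.290), fatty acid oxidation (0.241), heat shock (0.217) and pyrimidine synthesis (0.196). Of 504 members, 4 had a negative mean r with the rest of their list, named after their values were seen: URA10 (-0.382, pyrimidine synthesis), SSE2 (-0.338, heat shock), CTA1 (-0.0811, fatty acid oxidation) and ADE16 (-0.0449, purine synthesis). Of 22 lists tested, 21 passed, most at the smallest permutation p possible, 1e-04; sporulation had a mean r of 0.127 with p = 0.0984. The a-specific, alpha-specific and daughter cell separation scores fell into 2 clusters, with 49, 39 and 36 of 86 segregants in the lower cluster, so they were given no pooled value. With genes that had a value on every array, 10 of 11 lists passed. Heat shock did not, with a mean r of 0.0261 and an adjusted p of 0.428 against random lists.

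Joining the 1865 varying genes by their correlation gave 35 clusters of at least 5 genes, with 552 genes in all. The largest clusters held 73 genes each. General stress genes were enriched in the first of these, with 17 of the 25 in the background, and cytosolic ribosome genes in the other, with 24 of 31. A cluster of 65 genes held 13 of 17 ribosome biogenesis genes, and a cluster of 52 held 27 of 43 mitochondrial ribosome genes. A cluster of 29 held 9 of 20 amino acid starvation genes. The 8 histone genes fell in a cluster of 9 genes, and 6 of the 8 methionine and sulfur genes formed a cluster of their own. A list was enriched in 19 clusters by Fisher's exact test, and 5 sets of values permuted among segregants gave 0 clusters. Part of the clusters followed chromosomes, a count made after the data were seen: 7 clusters had at least 80 percent of their genes on chromosome 2 and 1 on chromosome 4, and 4 of these 8 were among the 19. Without the 6 segregants with a shifted chromosome there were 26 clusters, 0 of them mostly on a single chromosome by that limit, and 15 had an enriched list. The number of clusters was 53 with the tree divided at r = 0.6 and 19 at 0.8, 15 with Cy3-titled arrays alone and 11 among genes with a value on every array.

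Scores of the lists were also compared with each other. Ribosome biogenesis scores rose with cytosolic ribosome scores (r = 0.807, rho = 0.784) and fell as general stress scores rose (r = -0.766, rho = -0.822). Leucine and branched-chain scores rose with amino acid starvation scores (r = 0.785, rho = 0.776), as did lysine scores (r = 0.775, rho = 0.823). Histone scores rose with cytosolic ribosome scores at r = 0.636 and rho = 0.356. The first 4 had the smallest permutation p possible, 1e-05, for r and rho (adjusted p = 8.88e-05 for r and 0.000105 for rho, over 231 pairs), and the last had 1e-05 for r and 0.00091 for rho. Without the 2 segregants farthest from the median the values of r were 0.777, -0.778, 0.750, 0.919 and 0.561 in the order given. The first number of the segregant titles, whose meaning is not stated, split the segregants into 18 sets. With that number removed, r was 0.774, -0.790, 0.755, 0.753 and 0.603, and within the 5 sets of at least 6 segregants, r between ribosome biogenesis and general stress ran from -0.900 to -0.616. In all, 112 of 231 pairs passed, 58 positive and 54 negative.

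**Figure D3:**
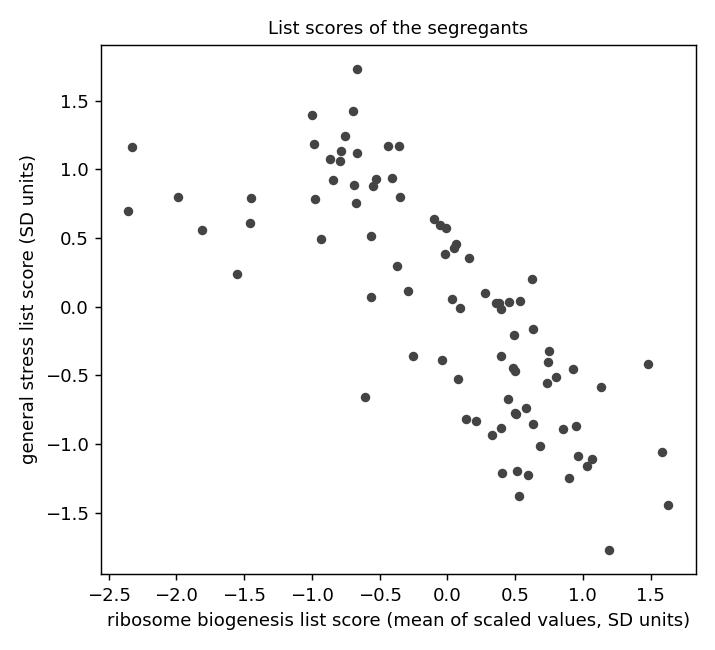
General stress list score against ribosome biogenesis list score, both in SD units, with 1 point for each of 86 segregants. The scores moved in opposition, with r = -0.766.

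Neighbouring genes were compared to find whether position on a chromosome goes with shared variation. Convergent neighbours had a mean r of 0.231 (SEM 0.0145, 449 pairs), divergent neighbours 0.172 (SEM 0.0146, 430 pairs) and neighbours on the same strand 0.104 (SEM 0.0112, 773 pairs). Convergent minus same-strand neighbours gave 0.127, and at most 0.0598 in 1000 permutations of orientation over pairs, a test added after the values were seen. Over 1652 adjacent pairs the mean r was 0.156, against 0.0164 in 10000 permutations of positions and at most 0.0412 in any of them (p = 1e-04, the smallest possible). Genes with consecutive probe numbers that were not neighbours had a mean r of 0.148. For genes on different arms the mean r was 0.0952 at 2 to 9 probe numbers apart, 0.0838 at 10 to 49 and 0.0538 at 50 to 199, against 0.0169 at 200 to 799, so nearness of probe numbers went with shared variation. In 4 of the 35 clusters more pairs lay under 200 probe numbers apart than in random sets of varying genes, a test added after the values were seen. These included the clusters with cytosolic ribosome and ribosome biogenesis genes, with 8.30 and 8.56 percent of pairs against 5.77 and 5.79 percent. With only pairs of members over 400 probe numbers apart, an alternative added likewise, 21 of 22 lists co-varied.

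Chromosome medians of the segregants, with every gene centred over segregants, gave a further view of position. In 6 segregants 7 chromosome medians passed a size of 0.5 log2 units. They were chromosome 2 in segregant replicates 61 (0.82), 37 (0.73), 51 (0.65) and 75 (0.64), chromosome 13 in 47 (0.73) and chromosomes 9 and 4 in 70 (0.69 and 0.67). The largest of the other chromosome medians had a size of 0.29. Without these 6 segregants 1481 genes passed the variance test, and the mean r of neighbouring genes was 0.114, with 0.194 for convergent, 0.127 for divergent and 0.0617 for same-strand neighbours.

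**Figure D4:**
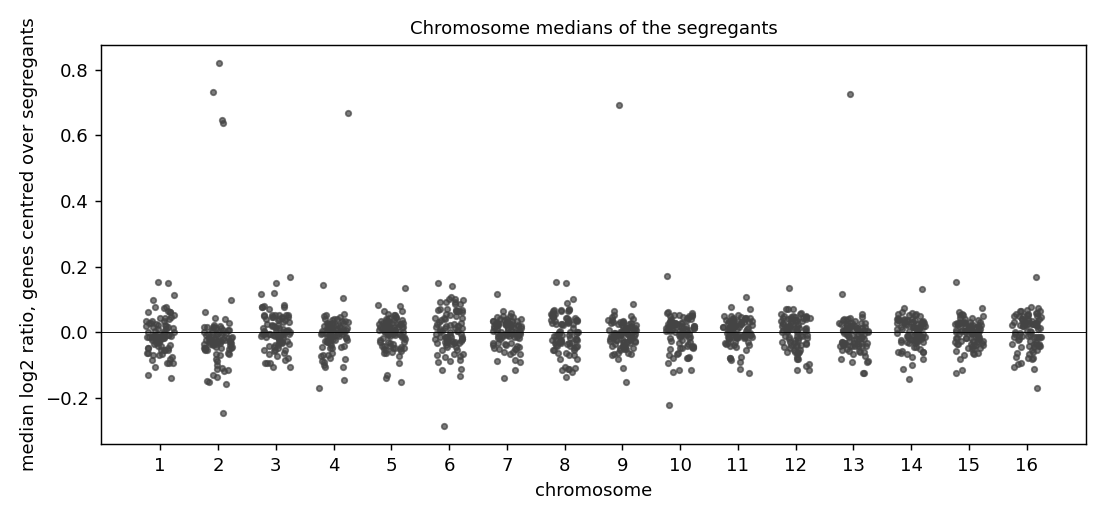
Median log2 ratio of the genes on each of 16 chromosomes, with genes centred over segregants and 1 point per segregant spread sideways for legibility. All 7 points above 0.5 came from 6 segregants, 4 of them on chromosome 2.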

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

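Tests chosen only after the result was seen were those on neighbours with probe numbers far apart, on genes 2 to 4 positions apart, on the printing order within chromosome arms, on the orientation of neighbours, on convergent neighbours, and all that left out segregants with a shifted chromosome.

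A signal outside the named genes came from probes without a gene name, of which 64 of 309 tested were called between RM11 and BY4716, 31 higher and 33 lower in RM11, or 20.7 percent against 26.7 percent of genes. In the comparison of BY4716 with the pool of the same strain limma called 0 of these probes, and 53 had an unadjusted p under 0.05, where 15.45 would arise by chance.

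Whole chromosomes were shifted in 6 of 86 segregants. Chromosome 2 had medians from 0.64 to 0.82 in 4 of them, over 218 genes. Noise of single arrays and printing order were argued against, since chromosome medians of both arrays correlated at 0.825 and genes of the same arm with distant probe numbers kept a mean r of 0.0635. Genes on opposite arms of a chromosome had a mean r of 0.0668, above 0.0202, the highest of 1000 permutations, and without the 6 segregants it was 0.0198, close to the 0.0174 of genes on different chromosomes. A candidate explanation is an extra copy of these chromosomes in single segregants, a hypothesis that was not tested on DNA.

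Directly adjacent genes varied together beyond that level, with a mean r of 0.156 in all segregants. Printing order had met the criterion set for it beforehand, with 0.148 for consecutive probe numbers, but neighbours with probe numbers over 400 apart kept 0.154, which argues against it as the cause. The criteria set beforehand for adjacency and for co-inheritance of linked loci, 0.0642 at 5 to 10 positions and 0.0685 at 200 to 250, were void because shifted chromosomes raised both values, as they did 0.0741 at 2 to 4 positions. Without the 6 shifted segregants co-inheritance was argued against as the whole cause, since the mean r fell from 0.114 for adjacent genes to 0.0314 at 2 to 4 positions, just above the highest permutation of 0.0308, and 0.0185 at 5 to 10, inside the permutations, and convergent exceeded same-strand neighbours by 0.132, against at most 0.0611 in 1000 permutations of orientation. Shared promoters were argued against as the whole cause by the 0.194 of convergent genes, which share none, against at most 0.0591 in permutations. Overlapping transcripts and shared probe sequence cannot be told apart, since no test separated them. In all segregants, 0.140 remained once same-number opposite-strand names and pairs with r over 0.8 were left out. That value still holds the shifted chromosomes and left out pairs by their own r. Smaller parts from promoters and from short-range co-inheritance stay open.

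General stress and ribosome biogenesis genes moved in opposition across segregants, with r = -0.766. Batches marked by the first title number were argued against, since r was -0.790 with that number removed, as was noise of single arrays, since the scores of both arrays of a segregant correlated at 0.975 or above. Differences between cultures in growth at harvest cannot be told apart from inherited differences, because the F test of the list difference had p = 0.151 with only 2 pairs of parental cultures. Inherited differences between segregants stay open and were not tested.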

How the results depend on the processing

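Alternatives added after the data were seen left out segregants with arrays correlating under 0.5 or with a shifted chromosome, compared only probes with numbers over 400 apart, or permuted genes within arms. Of 101 alternative counts and values of the main results, 65 stayed within 1.5 times the main count or on the same side of the threshold. The added alternatives were among these, with 0.114 to 0.156 for neighbouring genes, which stayed past the threshold under every alternative run. Of the 112 pairs of list scores, 90 to 107 passed again with the same sign, within totals of 98 to 113 of 231 to 300 pairs tested. With a block for the culture number 830 genes and 9 lists passed; this number did not establish pairs, since deviations of same-numbered cultures correlated at 0.189 across genes of only 2 pairs.

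With Cy3-titled arrays alone 533 genes passed between parents, 631 the variance test, and 15 clusters were found; with Cy5-titled arrays alone 13 genes passed in BY4716 against the pool, 3403 the variance test, and 16 lists between parents. Quantile normalization gave 850 genes in BY4716 against the pool, 835 against the midpoint and 14 lists, and the shift of the general stress list reversed to -0.33, against 0.26. A minimum of 1.5-fold left 406 genes, since it only removes calls. Genes with a value on every array, which are fewer, gave 219 between parents, 580 in the variance test, 10 lists that co-varied and 11 clusters. The error between dyes gave 3100 in the variance test. Looser and stricter limits gave 53 and 19 clusters of genes and, by construction, 104, 32 and 101 genes in 2 clusters. An estimated correlation left 0 lists. Leaving out 1 parental culture gave 199 to 1797 genes between parents, 0 to 1396 in BY4716 against the pool, 139 to 3636 in the variance test, 47 to 1545 against the midpoint and 11 to 14 lists. For all of these the cause was not tested, except where the construction of the alternative gives it. All alternatives planned were run. Signal over background was not used here, so its limits on single genes are unknown.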

Other observations

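The genes LYS2, STE6 and CYB2 had values on all 4 RM11 arrays and on none of the BY4716 arrays, with RM11 means of 5.40, 4.08 and 2.54. LYS2 is deleted in BY4716 and STE6 exports a-factor, so both follow from the genotypes, whereas CYB2, chosen after its values were seen, encodes the mitochondrial lactate dehydrogenase. As the pool is BY4716 too, the sizes of the ratios of LYS2 and STE6 depend on the lower limit of the pool signal. The ratio of CYB2, also without a value on any BY4716 array, may depend on that limit as well. The opposite case, values on BY4716 arrays alone, was found for 0 genes.

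The genes farthest above the midpoint did not fall into 2 clusters. For YBR012W-B, YBL005W-A, YDR170W-A and YMR045C the segregant means were -0.71, -0.90, -0.91 and -0.68, and for HXT13 -0.82. The RM11 means of these genes were -7.51, -7.49, -5.99, -5.10 and -4.65. HXT13 fell in a cluster of 7 genes with YDR170W-A, YMR045C, YBL005W-A, YMR158C-A, BPH1 and MOB2, where its mean r with the other members was 0.857. That of BPH1 was 0.873 and that of MOB2 0.712, and no other hexose transporter gene was in the cluster. The value of MOB2 averaged 2 probes that did not agree across segregants (r = -0.0565, permutation p = 0.635, rho = -0.0890, p = 0.468), so its place in the cluster is not that of both probes. Why these genes varied together was not tested.

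Of 10 genes with a difference between parents for both of their 2 probes, 4 had probes that differed in sign, a count made, like the correlations below, after the values were seen. They were FLO8 (0.11 and -0.26), NET1 (-0.08 and 0.13), MPS3 (-0.05 and 0.08) and YPR089W (-0.01 and 0.10). Most of these differences were near the median SE over genes of 0.09, so their signs carry little weight. Across segregants the 2 probes agreed for NET1 (r = 0.784, rho = 0.779, permutation p = 1e-04 for both) and YPR089W (r = 0.635, rho = 0.670, 1e-04 for both). No agreement was found for FLO8 (r = -0.0899, p = 0.430, rho = 0.0108, p = 0.922) and MPS3 (r = 0.0330, p = 0.769, rho = 0.0167, p = 0.880). Over all 40 genes with 2 probes, r was under 0.5 for 16, so part of the averages joined probes that disagreed.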
